A study of Homo sapiens with 12 samples.

How the data were processed

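RNA was measured by stranded mRNA sequencing in HAdpc-29-E7-TERT, a human line of adipose-derived stem cells from the Japanese JCRB cell bank, in 4 groups of 3 libraries each. Per the labels, the groups were vehicle, 1.0 mM butyrate (BA), the cytokines TNF-α at 3.0 pg/mL with IFN-γ at 10.0 pg/mL, and BA with both cytokines, all for 72 h. The labels call the samples of a group biological replicates. Cells grew in POWEREDBY10 medium, RNA was taken with a NucleoSpin column kit and libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and the genome build GRCh38, with no role or order. The counting tool, its strand setting and the annotation release are not given in the sources used here.

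Samples were grouped by the treatment field, which names the same group as the library name in all 12 samples. The titles of the 6 cytokine samples name the opposite cytokine group. Table columns carry the library names and were matched through them. No sample was regrouped from its values.

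The expression table holds 1839 genes. The authors deposited raw read counts per gene in whole numbers, with a lowest value of 1. Each of the 1839 genes had a fold change of at least 2 and a raw p under 0.05 in at least 1 of the 6 comparisons that the authors deposited, a selection read from the values. The authors also deposited FPKM and TPM values, scaled over all genes, so the table holds 2.38% to 4.17% of each library's TPM. Normalized log2 values per library were deposited as well, pulled towards each gene's mean by a method not stated, together with log2 group means and standard errors of log2 fold changes. Per the file headers, each comparison also has a mean normalized signal, a signed fold change, a test statistic that is a score without fixed range, a raw p-value and a Benjamini-Hochberg adjusted p-value. The authors adjusted over between 16756 and 17433 genes, as the ranks in the adjusted p-values imply, which is far more than the table holds. Pathway and gene ontology tables that the authors deposited give gene numbers and enrichment p-values for the selected genes as a whole, not by comparison or direction.

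Selection decides what can be read from the table. Most members were chosen because they moved with BA, so the number of genes called in a BA comparison is set in part by the selection, and the content lies in direction and size. The p-values given here are those of a selected set. The authors' adjusted p-values, over all genes they tested, are given for the leading genes of BA against vehicle, of cytokines against vehicle and of BA with cytokines against cytokines, and otherwise as counts. No enrichment test was run. Genes outside the table are not analysed here, so a gene list is described only by its members in the table. Total library depth is not given in the sources used here. The counts inside the table summed to between 962470 and 2256663 per library, which is not depth.

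Library scaling followed the plan for a selected table. The authors' mean normalized signal is an exact combination of the 12 count columns, with a largest residual of 5.1e-15, and gave 1 size factor per library, from 0.918 to 1.139. A scaled count is a count divided by that factor. These factors were computed by the authors before the selection. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, all 12 libraries in 1 fit with a mean per group, library size 1e+06 times the size factor, no filter), and p-values were adjusted by Benjamini-Hochberg (BH) over the 1839 genes. A gene was called at an adjusted p under 0.05. The comparisons were BA against vehicle, cytokines against vehicle, BA with cytokines against cytokines, BA with cytokines against vehicle, and the interaction, which is the BA change with cytokines minus the BA change without. BA with cytokines against BA was added after the data were seen. Log2 changes from this fit lay within a median distance of 0.003 or less from the authors' deposited log2 fold changes in each comparison of groups. Means are given with SD over 3 libraries and log2 changes with standard errors.

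The test was checked on simulated counts with the means and library sizes of the 1839 genes. Changes of 4-fold were recovered in 97% of genes for BA against vehicle, 98.5% for cytokines against vehicle and 74.2% for the interaction. Changes of 2-fold were recovered in 70.1%, 56.7% and 37.3%, and changes of 1.5-fold in 28.4%, 31.3% and 9%. For BA with cytokines, recovery at 2-fold was 64.2% against cytokines and 53.7% against vehicle. Of 1639 unchanged genes, between 0.12% and 0.37% were called per comparison. The simulated genes passed no selection, so these shares are not error rates of the calls in the selected table.

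Before the data were examined, the tests, the alternatives and 29 gene lists with 613 genes were written down. The lists cover interferon response, antigen presentation, NF-κB and TNF response, immunomodulators of mesenchymal stem cells, complement, genes induced by histone deacetylase (HDAC) inhibitors, HDAC and sirtuin genes, butyrate receptors and oxidation, adipogenic, osteogenic and chondrogenic genes, stem cell surface markers, collagen matrix, matrix proteases, trophic factors, cell cycle, DNA replication, p53 targets, cholesterol synthesis, metallothioneins, endoplasmic reticulum stress, hypoxia and glycolysis, mitochondrial regulators, neuronal genes, markers of smooth muscle, endothelial cells, leukocytes and epithelium, and a list of handling and stress genes. The table holds 101 of the listed genes, in 23 of the lists. Lists were counted by members called over all genes and by members adjusted over the list alone. The interferon list and the NF-κB and TNF list were also tested as sets, an addition made after the data were seen, with limma's fry, which asks whether the genes of a set move, on balance, one way, with BH adjustment over 12 such tests (2 lists in 6 comparisons), and again with TMM and total-count scaling inside the table. Only members that passed the authors' selection entered these set tests, which favours small p-values in the BA comparisons. Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls per comparison among called, named genes with a mean scaled count of at least 8 and no overlap between groups (4 each way for BA with cytokines against vehicle), up to 4 members per list with the smallest p, 13 genes named in all cases (5 are in the table), and for the interaction the 5 smallest p-values in each direction. Genes named outside that rule were chosen after their values were seen: TERT, RNA45SN3, PTX3, SOD2 and F3 throughout, GBP5, CCL5, CIITA, IER3, NFKBIZ, EGR1, FOS, DUSP1, EGR2, FOSB, RCAN1, TRNS1 and list members named for their exception wherever they rank below the rule's limits.

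Coordinates come from the RefSeq table of GRCh38.p14, the build that the submitters' notes name, through the NCBI gene ID, and 1785 of 1839 genes matched. Overlapping read-through models and antisense genes are marked as uncertain, because the strand setting of the counting is not known. Replicate libraries of a group differed from each other by more than sampling noise (chi-square per degree of freedom from 4.4 to 38.42), so no library was counted as a duplicate.

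The alternatives were TMM scaling, total-count scaling and DESeq2 1.42.0 size factors computed inside the table, a mean count of at least 10, only the groups compared, the replicate number as a block, limma-voom (limma 3.58.1), BH adjustment over the number of genes the authors tested, a fold change of at least 2, and each library left out in turn. Added after seeing the data were limma on log2(TPM + 0.1), DESeq2 with the authors' size factors, and leaving out the 3 libraries with a scaled count of 45S ribosomal RNA (RNA45SN3) above 20000, which leaves 1 BA library, assumed there to vary like the other groups. Scalings inside the table set the centre of genes chosen for change near 0 and so measure a gene relative to the other selected genes.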

Results

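The series asked how gene expression in a human adipose-derived stem cell line changes with butyrate (BA), a short-chain fatty acid that inhibits histone deacetylases, alone and together with the inflammatory cytokines TNF-α and IFN-γ. The line, HAdpc-29-E7-TERT, carries E7 and TERT in its name. RNA was sequenced from 12 libraries, 3 in each of 4 groups: vehicle, 1.0 mM BA, cytokines (TNF-α at 3.0 pg/mL with IFN-γ at 10.0 pg/mL) and BA with cytokines, after 72 h. The deposited table holds 1839 genes that the authors had selected for a change in at least 1 of 6 comparisons. Counts inside the table summed to between 990802 and 1018753 in vehicle, 2148500 and 2256663 in BA, 962470 and 1162371 in cytokine and 1899632 and 2171958 in BA with cytokine libraries. FN1, which encodes the matrix protein fibronectin, took between 41.6% and 51.6% of these counts. The 45S ribosomal RNA precursor (RNA45SN3) had scaled counts of 33484 in vehicle library 2, 35163 in BA library 2 and 61711 in BA library 3, against 3998 to 6805 in the other libraries.

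Titles of the 6 cytokine samples name the opposite cytokine group from their treatment field and library name, and groups here follow the latter pair. Genes called in BA against vehicle, which uses neither cytokine group, served as a check. The 1281 genes higher with BA had a median log2 difference of 1.20 between the groups taken as BA with cytokines and cytokines alone, and 97.7% of them were positive. The 242 genes lower with BA had a median of −1.0, and 95.9% were negative. IL6, for example, had a mean scaled count of 3778 ± 84.8 (SD, n = 3) in the group taken as BA with cytokines and 661.4 ± 8.34 (SD, n = 3) in the group taken as cytokines alone.

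What BA did without added cytokines was the first question. BA lowered interferon-induced genes and raised genes of inflammatory chemokines and cytokines. IL6, the gene of the cytokine interleukin 6, rose 6.76-fold (log2 2.76 ± 0.08, SE). MX1, an antiviral GTPase induced by interferon, fell by 2.55 ± 0.28 (SE) on the log2 scale. The scaled count of IL6 (gene ID 3569, chromosome 7, 22727200 to 22731998, GRCh38) went from 483.6 ± 42.5 in vehicle to 3269 ± 27.3 with BA (SD, n = 3). That of MX1 (gene ID 4599, chromosome 21, 41420558 to 41459214) went from 8401 ± 1860 to 1438 ± 204 (SD, n = 3). EEF1A2, the form of translation elongation factor 1 alpha used in neurons and muscle (gene ID 1917, chromosome 20, 63488014 to 63499083), rose 18.3-fold, from 73.81 ± 3.49 to 1355 ± 109 (SD, n = 3). ADH1B, an alcohol dehydrogenase abundant in fat (gene ID 125, chromosome 4, 99304971 to 99321401), dropped by 3.30 ± 0.16 (SE) on the log2 scale, from 493 ± 29 to 50.09 ± 1.08 (SD, n = 3).

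Other large rises with BA were those of DIPK1B (log2 4.16 ± 0.32, SE), CRMP1 of neurons (4.15), the liver transcription factor CREB3L3 (4.01), the transcription factor NFE2L3 (3.99), the small GTPase RAB37 (3.96) and the cell surface proteoglycan GPC3 (3.79). BLOC1S5-TXNDC5 had the largest estimate, 5.39 ± 1.64 (SE), but it is a read-through model that overlaps other genes, so its reads are uncertain. After ADH1B and MX1, the largest falls were in IFI44L (log2 −2.44), NAALADL2 (−2.42), MX2 (−2.26), the mucin gene MUC19 (−2.04), RSAD2 (−2.03) and IRAIN (−2.01), an antisense RNA whose reads cannot be assigned without knowing the strand setting. IFI44L, MX2 and RSAD2 are interferon-induced.

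By edgeR's quasi-likelihood test with BH adjustment, 1523 of 1839 genes were called in BA against vehicle, 1281 higher (84.1%) and 242 lower. Of these 1523, 1445 had no overlap between the 3 BA and 3 vehicle libraries. Chance gives 10% for a gene not chosen by its values. A call already favours such separation, so the number adds no support. Adjusted p was 1.47e-25 for IL6, 8.81e-25 for EEF1A2, 1.41e-18 for ADH1B, 3.61e-05 for MX1 and 0.0146 for BLOC1S5-TXNDC5 (edgeR quasi-likelihood, BH). For EEF1A2, ADH1B, MX1 and BLOC1S5-TXNDC5 the authors' deposited table gave adjusted p = 6.99e-201, 1.87e-90, 7.48e-19 and 0.000321, and it lists IL6 at 0. In the authors' deposited table, 1394 of the 1523 genes had an adjusted p under 0.05. The ranks in the adjusted p-values of the authors' deposited table imply that at least 7244 of all genes tested did. At a fold change of 2 and raw p under 0.05, 1085 genes were higher and 175 lower in the authors' deposited table. Because the table was selected for change, the split depends on the scaling: scalings computed inside it called 315 higher and 380 lower (TMM), 399 and 348 (total count) or 323 and 373 (DESeq2), while log2 TPM, scaled over the whole library, gave 83.2% higher. RNA45SN3 itself was not called between BA and vehicle (log2 1.17 ± 0.89, SE; adjusted p = 0.244, edgeR quasi-likelihood, BH), except without vehicle library 2 (2.5, adjusted p = 0.0296, same test), and without the 3 libraries high in it 1126 genes were called, 977 higher and 149 lower, with the calls of BLOC1S5-TXNDC5 (4.48), MUC19 (−1.55), IRAIN (−1.18) and KLF15 (−0.84) lost. BLOC1S5-TXNDC5 also lost its call under TMM (4.27) and total-count scaling (4.41) inside the table, with limma-voom (5.90) and with BH over the genes the authors tested, and its adjusted p over these and the fit without the 3 libraries ran from 0.058 to 0.168 (edgeR quasi-likelihood or limma-voom, BH).

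Interferon genes were lower with BA as a group. Of the 44 genes in the interferon list, 24 were in the table, and 23 of these fell and 1 rose, with the same counts adjusted over the list alone and under each of the scalings computed inside the table. The median log2 change was −1.26, and −2.37 (TMM), −2.23 (total count) and −2.37 (DESeq2) with scaling inside the table, where the median of all table genes, 1.11, is set near 0. The smallest p-values belonged to DTX3L, which ubiquitinates histones in antiviral defence (log2 −1.12 ± 0.07, SE), APOL6 (−0.94 ± 0.07), IRF9, the DNA-binding part of the ISGF3 complex (−1.18 ± 0.09), and SAMD9L (−1.47 ± 0.09). IDO1, which breaks down tryptophan and restrains T cells, fell by 0.87 ± 0.19 (SE) on the log2 scale, from 175.4 ± 33.9 to 96.21 ± 14 (SD, n = 3). The exception was GBP5, a guanylate-binding protein, which rose (log2 2.05 ± 0.20, SE). Without the 3 libraries high in RNA45SN3, of which 2 are BA and 1 is vehicle, 22 of 24 were lower and the median was −1.26.

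Antigen presentation genes went both ways. Of 6 members in the table out of 30, 3 rose, 2 fell and 1 was not called, also when adjusted over the list alone. HLA-DMA, which loads peptides on class II molecules, rose 5.35-fold (log2 2.42 ± 0.15, SE), HLA-DPB1 rose by 1.14, and CD74, the invariant chain, by 1.00. The immunoproteasome subunit PSMB10 (log2 −1.07 ± 0.13, SE) and CIITA, the master regulator of class II genes (−1.30 ± 0.40), fell. Relative to the other selected genes (TMM inside the table), 2 of the 6 were positive, of which 1 was called higher, CD74 was at log2 −0.11 and HLA-DPB1 at 0.03.

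NF-κB and TNF response genes were higher with BA as a group. Of 40 listed genes, 19 were in the table, and 18 rose and 1 fell, also adjusted over the list alone, with a median log2 change of 1.38, against 1.11 for all table genes. Scaled inside the table the median was 0.27 (TMM), 0.41 (total count) and 0.27 (DESeq2). Relative to the other selected genes (TMM inside the table), 16 of 19 were still positive, 9 were called higher, and PTGS2 and LIF turned, of which only PTGS2 did so under total count. CXCL8, the neutrophil chemokine interleukin 8, went from 1511 ± 125 to 8727 ± 454 (SD, n = 3), a rise of 5.78-fold. CXCL1 rose from 3313 ± 70.2 to 13700 ± 384 and CXCL6 from 350.3 ± 20.7 to 1880 ± 57.5 (SD, n = 3). CCL5, a T cell chemokine also induced by interferon, fell (log2 −0.54 ± 0.20, SE), a call lost without vehicle library 1 (−0.42) or BA library 1 (−0.43). Without the 3 libraries high in RNA45SN3, 18 of 19 were again higher.

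Of 8 immunomodulators of mesenchymal stem cells in the table (33 listed), 7 rose and IDO1 fell, also adjusted over the list alone. They included IL6, the secreted glycoprotein STC1 (log2 2.27 ± 0.09, SE), CD274, the gene of the checkpoint ligand PD-L1 (279.4 ± 32.7 to 650.1 ± 33.7, SD, n = 3) and PTGS2, the inducible cyclooxygenase (log2 0.96 ± 0.11, SE). Of the 8, 4 were positive under TMM inside the table and 3 called higher. PTGS2 was at log2 −0.14 there, and CD274 lost its call under each scaling inside the table, at 0.11 (TMM), 0.25 (total count) and 0.11 (DESeq2).

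Lineage genes in the table rose with BA in most cases, as did 1281 of all 1839 table genes. A rise in most members therefore does not set these lists apart. The table held 5 of 29 listed adipogenic, 5 of 19 osteogenic, 3 of 14 chondrogenic and 2 of 29 collagen genes. It held 2 of 22 protease, 6 of 34 trophic, 3 of 17 surface and 4 of 28 neuronal genes. The numbers in brackets are those still positive and those called higher relative to the other selected genes (TMM inside the table). Of 5 adipogenic genes, 4 rose (3, 0), among them PPARG, the master regulator of fat cell formation (116.5 ± 6.4 to 279.1 ± 5.71, SD, n = 3), and the fatty acid transporter CD36 (log2 1.31 ± 0.15, SE), while KLF15 fell (−1.08 ± 0.26). PPARG was at log2 0.15 and CD36 at 0.21 under TMM, neither of them called. All 5 osteogenic genes rose (4, 1; ALPL turned), led by SPP1, the gene of osteopontin (log2 2.51 ± 0.13, SE), as did all 3 chondrogenic genes (2, 1), led by COL11A1 (1.86 ± 0.17). Both collagen and matrix genes in the table rose (2, 1), FN1 by log2 1.18 ± 0.03 (SE) along with COL11A1, as did both protease genes (2, 1). All 6 trophic factors rose (4, 0), with INHBA at log2 1.21 ± 0.06 and HBEGF at 1.24 ± 0.11 (SE). Under TMM, FN1 was at 0.07, INHBA at 0.10 and HBEGF at 0.13, none of them called. Of 3 stem cell surface markers 2 rose (1, 1), and all 4 neuronal genes rose (2, 2), with SCG5 at log2 2.39 ± 0.12 and SCG2 at 1.40 ± 0.11 (SE).

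Markers of other cell types in the table also rose with BA, with the same numbers in brackets. The table held 2 of 11 listed smooth muscle, 3 of 12 endothelial, 1 of 14 leukocyte and 4 of 11 epithelial markers. Both smooth muscle genes rose (1, 1), with desmin (DES) from 120.7 ± 7.52 to 651.3 ± 72.8 (SD, n = 3). All 3 endothelial genes rose (3, 1), with CDH5 at log2 1.81 ± 0.21 and FLT1 at 1.24 ± 0.08 (SE). The leukocyte gene PTPRC went from 52.21 ± 27.1 to 254.1 ± 42.2 (SD, n = 3) and was also called higher under TMM. All 4 epithelial genes rose (3, 1), with KRT19 at log2 1.83 ± 0.24 and CDH1 at 1.43 ± 0.15 (SE). Under TMM, FLT1 (0.13) and CDH1 (0.32) were not called. The single members of the HDAC inhibitor list (HSPA2, log2 1.54 ± 0.07, SE) and of the metallothionein list rose and stayed positive, those of the complement and of the butyrate receptor and oxidation lists rose and turned, and the p53 target TP53I3 fell (−1.11 ± 0.07, SE). All 3 mitochondrial regulators rose (1, 0). The 4 handling and stress genes in the table rose (2, 2), with the immediate-early transcription factor EGR1 at log2 2.65 ± 0.07, FOS at 1.80 ± 0.11 and the phosphatase DUSP1 at 1.11 ± 0.07 (SE), the last of which was at 0.00 under TMM. Every count here was the same adjusted over the list alone. In fits without 1 library, 4 list members lost their call at least once, CCL5 in 2 of 12 fits, CEBPA (0.66 to 1.13) and NTF3 (0.83 to 0.87) in 4 and FOSB (0.41 to 0.59) in 7. In the lists on HDAC and sirtuin genes, cell cycle, DNA replication, cholesterol synthesis, endoplasmic reticulum stress, and hypoxia and glycolysis, 6 in all, no member was in the table.

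**Figure D1:**
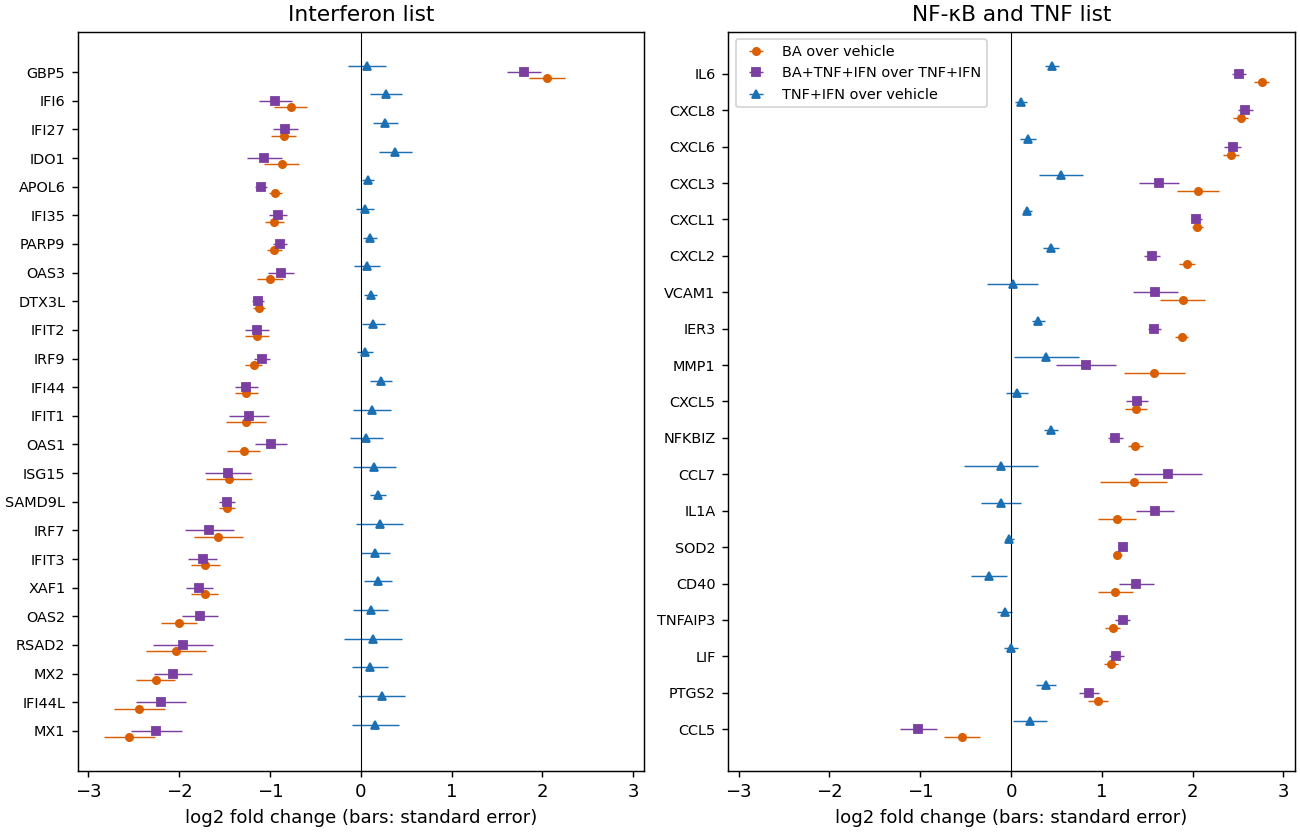
Log2 change with standard error of each table member of the interferon list (left) and the NF-κB and TNF list (right) for BA over vehicle (circles), BA with cytokines over cytokines (squares) and cytokines over vehicle (triangles), from 3 libraries per group. Interferon members other than GBP5 lie below 0 in both BA comparisons, and NF-κB members other than CCL5 lie above 0, although PTGS2 turns in both under each scaling inside the table, LIF in the first and MMP1 in the second under TMM.

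What the cytokines did alone was the next question. At these doses and after 72 h few of the selected table genes were called, and the smallest p-values belonged to the immediate-early genes EGR1 and FOS. EGR1, a transcription factor induced within minutes of a stimulus (gene ID 1958, chromosome 5, 138465479 to 138469303), rose 3.85-fold, from 1073 ± 41 in vehicle to 4133 ± 204 with cytokines (SD, n = 3). FOS, a subunit of the AP-1 transcription factor (gene ID 2353, chromosome 14, 75278828 to 75282230), rose 3.73-fold, from 212.1 ± 20.6 to 790.4 ± 33.4 (SD, n = 3). DUSP1 rose by log2 0.54 ± 0.07, IL6 by 0.45 ± 0.08, the NF-κB regulator NFKBIZ by 0.44 ± 0.08, F3, the gene of tissue factor, by 0.36 ± 0.06, and RCAN1, an inhibitor of calcineurin, by 0.32 ± 0.06 (SE).

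The test called 17 genes, 16 higher and 1 lower, and 251 had an unadjusted p under 0.05. Each of the 17 was without overlap between the groups, which a call already favours (10% for a gene not chosen by its values). Adjusted p was 6.56e-22 for EGR1, 1.27e-15 for FOS, 2.22e-06 for DUSP1 and 0.000444 for IL6 (edgeR quasi-likelihood, BH). In the authors' deposited table, adjusted p was 9.66e-210, 4.17e-78, 2.29e-15 and 5.31e-07 for these 4 genes, and 12 of the 17 were under 0.05. The ranks in the adjusted p-values of the authors' deposited table imply that at least 26 of 17433 genes tested were under that threshold. Only 12 of them are in the table, so the others could not be analysed here. By fold change and raw p, 101 table genes passed the authors' selection in this comparison. The count rests on single libraries: it was 8 without vehicle library 3, 9 without vehicle library 1 or 2, 11 and 10 without cytokine library 2 or 3, and 23 without cytokine library 1. RCAN1, DUSP1, EGR1, F3, FOS, IL6 and NFKBIZ were called in all 6 of these fits.

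Among other called genes, the early growth response gene EGR2 had log2 1.66 ± 0.36, TPTEP2-CSNK1E, a read-through model, 1.92 ± 0.42, RN7SL4P 1.56 ± 0.36, the carnosine synthase CARNS1 0.61 ± 0.16 and TTC3P1 −1.54 ± 0.39 (SE). Without vehicle library 1 all 5 lost their call (1.38, 1.76, 1.52, 0.55 and −1.22). Calls were also lost without vehicle library 3 for all 5 (1.37, 2.09, 1.58, 0.62 and −1.61) and without cytokine library 3 for all but EGR2 (1.5, 1.27, 0.63 and −1.44). Without vehicle library 2, TPTEP2-CSNK1E (1.94), RN7SL4P (1.58) and CARNS1 (0.67) lost it, without cytokine library 2 all but TPTEP2-CSNK1E did (EGR2 1.60, RN7SL4P 1.34, CARNS1 0.66 and TTC3P1 −1.61), and without cytokine library 1 CARNS1 (0.55) and TTC3P1 (−1.56) did. In the authors' deposited table, adjusted p was 0.00427 for EGR2, 0.0244 for TPTEP2-CSNK1E and 0.0105 for RN7SL4P, and 0.0917 and 0.132 for CARNS1 and TTC3P1.

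Of 19 NF-κB and TNF genes, 4 rose (IL6, NFKBIZ, the chemokine gene CXCL2 and IER3) and 6 passed when adjusted over the list alone, with a median log2 change of 0.18. CXCL2 had log2 0.44 ± 0.09 and IER3 0.30 ± 0.07 (SE), and the call of CXCL2 was lost without vehicle library 2 (0.35) or cytokine library 3 (0.42). Of the 6 fits without a vehicle or cytokine library, IER3 kept its call only in that without cytokine library 2, with 0.28, 0.29 and 0.32 without vehicle library 1, 2 or 3 and 0.27 and 0.25 without cytokine library 1 or 3. Of the 8 immunomodulators only IL6 rose, with 2 passing when adjusted over the list alone, and 3 of 4 handling and stress genes rose (EGR1, FOS and DUSP1, not FOSB). None of the 24 interferon genes was called by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, although all 24 estimates were positive with a median of 0.14; IDO1 had log2 0.38 ± 0.18, SAMD9L 0.19 ± 0.09, IFI44 0.22 ± 0.12 and MX1 0.16 ± 0.26 (SE). These 24 are the genes of 44 listed that passed the authors' selection, and 23 of them fell with BA. The other listed genes are not in the table, so this result cannot show whether the cells responded to IFN-γ. PTGS2 (0.39 ± 0.11), CD274 (0.13 ± 0.11) and PPARG (0.25 ± 0.16) were not called either. In every other list with members in the table, no member was called.

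**Figure D2:**
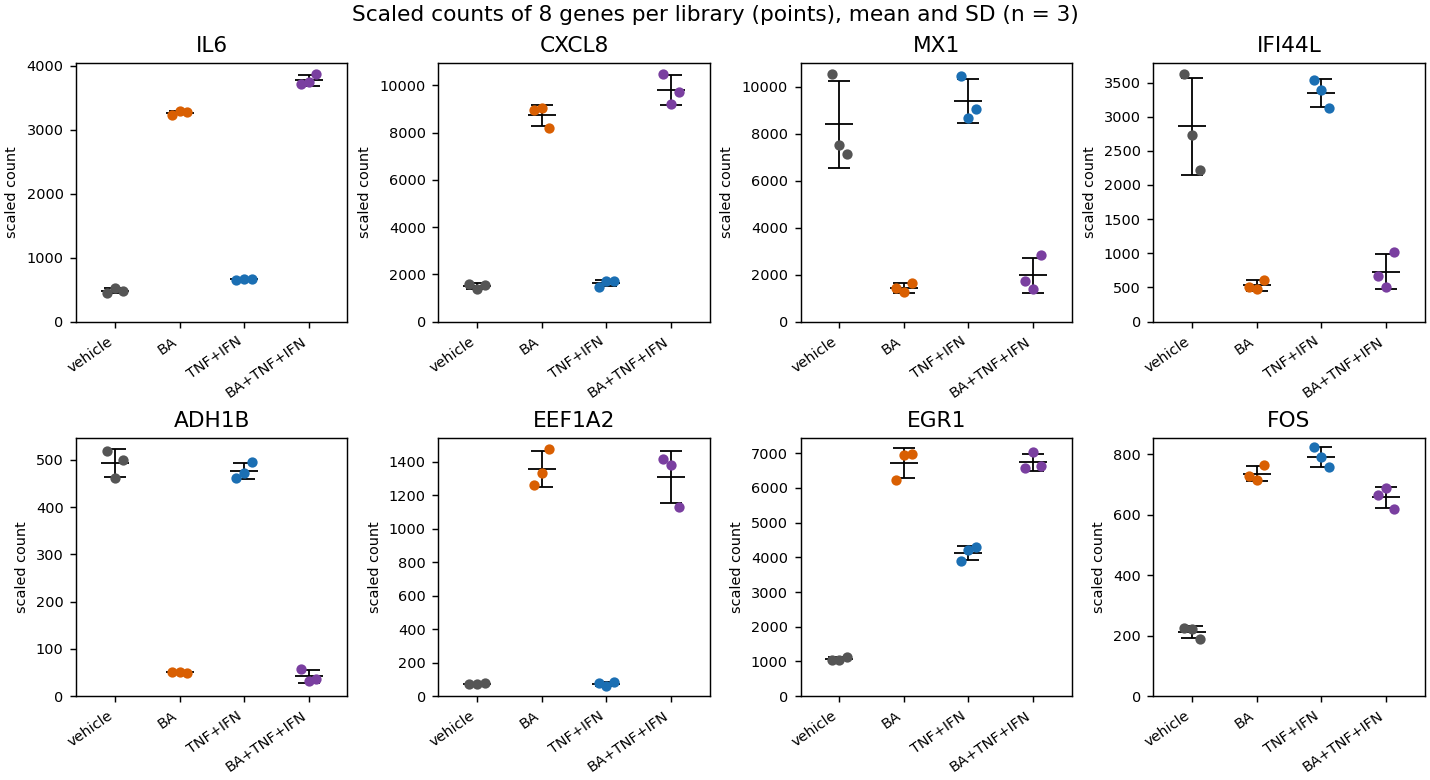
Scaled counts per library (points) with mean and SD (n = 3) of IL6, CXCL8, MX1, IFI44L, ADH1B, EEF1A2, EGR1 and FOS in vehicle, BA, cytokine (TNF+IFN) and BA with cytokine groups. EGR1 was at 1073 in vehicle, 4133 with cytokines, 6719 with BA and 6735 with both, while IL6 and MX1 follow BA in both settings.

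How BA acted in cells that also had cytokines was asked by comparing BA with cytokines against cytokines alone. IL6 rose 5.71-fold, from 661.4 ± 8.34 to 3778 ± 84.8 (SD, n = 3), and MX1 fell by 2.25 ± 0.28 (SE) on the log2 scale, from 9396 ± 932 to 1980 ± 745 (SD, n = 3). EEF1A2 rose 17.7-fold, from 73.99 ± 11.9 to 1308 ± 156, and ADH1B dropped from 476.1 ± 17.5 to 42.24 ± 13.7 (SD, n = 3). The largest rises were in the sulfotransferase GAL3ST3 (log2 4.21 ± 0.34, SE), NFE2L3 (4.17), EEF1A2 (4.14), SERPINA5, the protein C inhibitor (3.90), HSPA12B (3.80), CRMP1 (3.64), RTBDN of the retina (3.50) and the tubulin TUBB4A (3.48). After ADH1B (−3.50), the largest falls were in the glycosyltransferase GALNT17 (−2.70), NAALADL2 (−2.35), the noncoding RNA LINC00294 (−2.26), MX1, USP30-AS1 (−2.20), an antisense RNA whose reads are as uncertain as those of IRAIN, IFI44L (−2.20) and MX2 (−2.07). GALNT17 had a low count with BA and cytokines, so the size of its fall is uncertain. LINC00294 lost its call without BA with cytokine library 1 (−1.89) or cytokine library 1 (−1.73).

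Here 1462 genes were called by edgeR's quasi-likelihood test with BH adjustment, 1210 higher (82.8%) and 252 lower. Of these, 1376 were without overlap between groups, which a call already favours (10% for a gene not chosen by its values). Scalings computed inside the table called 319 higher and 391 lower (TMM), 378 and 374 (total count) or 312 and 383 (DESeq2). In the authors' deposited table, 1337 of the 1462 had an adjusted p under 0.05. Adjusted p was 1.42e-24 for both IL6 and EEF1A2, 7.17e-19 for ADH1B and 8.37e-05 for MX1 (edgeR quasi-likelihood, BH). For EEF1A2, ADH1B and MX1 the authors' deposited table gave 3.6e-197, 2.03e-88 and 7.75e-15, and it lists IL6 at 0. None of the 6 libraries in this comparison was high in RNA45SN3.

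Of the interferon genes, 23 of 24 fell and GBP5 rose (log2 1.80 ± 0.19, SE), also adjusted over the list alone and under the scalings computed inside the table, with a median of −1.19, and −2.24 (TMM), −2.14 (total count) and −2.23 (DESeq2) there. DTX3L (−1.13 ± 0.07, SE), APOL6 (−1.10), IRF9 (−1.09), SAMD9L (−1.47) and IDO1 (−1.06 ± 0.19) were among them. Of the NF-κB and TNF genes, 18 of 19 rose and CCL5 fell (−1.02 ± 0.20, SE), also adjusted over the list alone, with a median of 1.55, against 1.06 for all table genes. Scaled inside the table the median was 0.50 (TMM), 0.59 (total count) and 0.50 (DESeq2), and 16 of 19 were positive under TMM, with PTGS2 and MMP1 turning. CXCL8 rose by log2 2.58 ± 0.08, CXCL6 by 2.44 ± 0.09 and CXCL1 by 2.04 ± 0.06 (SE). Of the immunomodulators, 7 of 8 rose, including STC1 (2.48 ± 0.09) and CD274 (1.07 ± 0.11, SE), with PTGS2 turning from 0.86 ± 0.11 (SE) to −0.19 under TMM inside the table, where 2 of the 8 were called higher. CD274 lost its call under each scaling inside the table, at 0.02 (TMM), 0.12 (total count) and 0.02 (DESeq2). Of the antigen presentation genes, 4 of 6 rose, led by HLA-DMA (2.5 ± 0.15, SE), 1 fell and 1 was not called, and 2 of 6 were positive and 1 called higher under TMM inside the table.

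In the other lists the numbers positive and called higher under TMM inside the table again stand in brackets. Only members in the table are counted, and 1210 of all 1839 table genes were called higher. Of 5 adipogenic genes 4 rose and 1 fell (2, 1), with PPARG (log2 0.88 ± 0.15, SE) at −0.17 under TMM, and of 5 osteogenic genes 4 rose (2, 1), led by SPP1 (2.39 ± 0.13, SE). All 3 chondrogenic (2, 1), 3 surface (2, 0), 4 neuronal (3, 1), 3 endothelial (2, 2) and 4 epithelial genes (2, 2) and all 6 trophic factors (5, 1) rose, as did both collagen (2, 2), both protease (1, 1) and both smooth muscle genes (1, 1), with PTPRC at 2.23 ± 0.24 and DES at 2.26 ± 0.14 (SE). FN1 rose by 1.21 ± 0.03 (SE). The single complement and HDAC inhibitor list members rose, the former turning under TMM, the p53 target fell, the members of the butyrate and metallothionein lists were not called, and 1 of 3 mitochondrial regulators rose (0, 0). Of the handling and stress genes, 3 of 4 rose (0, 0; 3 were called lower), with EGR1 at 0.70 ± 0.07 (SE) but −0.35 under TMM, and FOS fell (−0.26 ± 0.10, SE), a call lost without BA with cytokine library 3 (−0.22) or cytokine library 1 (−0.23). Every count here was the same adjusted over the list alone. Other list members whose call was lost in at least 1 of 12 fits without 1 library were HLA-DPA1 (0.79 to 0.90), MMP1 (0.76 to 0.80), NGFR (0.86 to 1.03) and CLDN4 (0.69 to 0.92). Calls were gained by CIITA (−0.97 to −0.94), ACSM3 (0.90 to 0.94), PPARGC1A (0.82) and CPT1B (0.62).

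The combined treatment was also set against vehicle. EEF1A2 (log2 4.15 ± 0.13, SE), CREB3L3 (4.05), DIPK1B (4.03) and GAL3ST3 (3.83) had the largest rises, and ADH1B (−3.55), NAALADL2 (−2.63), GALNT17 (−2.58) and LINC00431 (−2.15) the largest falls. The size of the GALNT17 fall is again uncertain, because its count with BA and cytokines was low. IL6 rose by log2 2.97 and MX1 fell by 2.09. The test called 1456 genes, 1228 higher and 228 lower, 1342 of them under an adjusted p of 0.05 in the authors' deposited table. Of the 1456, 1369 were without overlap, which a call already favours (10% for a gene not chosen by its values). Scalings computed inside the table called 318 higher and 364 lower (TMM), 389 and 346 (total count) or 312 and 361 (DESeq2). The interferon list had 23 of 24 lower, with a median of −1.04, and −2.10 (TMM), −2.0 (total count) and −2.11 (DESeq2) scaled inside the table. The NF-κB and TNF list had 18 of 19 higher, with a median of 1.60 against 1.07 for all table genes, and 0.53 (TMM), 0.64 (total count) and 0.52 (DESeq2) scaled inside the table, where 10 were called higher under TMM. RNA45SN3 had a log2 change of −1.36 ± 0.90 (SE) and was not called. With DESeq2 size factors computed inside the table it was called lower (−2.42, adjusted p = 0.00693, DESeq2, BH). Vehicle library 2, high in RNA45SN3, is part of this comparison. Without it and the 2 BA libraries 1336 genes were called. The other lists are given by members called higher, with the numbers positive and called higher under TMM inside the table in brackets: 4 of 6 antigen presentation (2, 1), 7 of 8 immunomodulator (6, 2), 3 of 5 adipogenic (2, 0), 4 of 5 osteogenic (2, 1), 3 of 3 chondrogenic (2, 1), 2 of 3 surface (1, 0), 6 of 6 trophic (5, 1), 4 of 4 neuronal (2, 1), 3 of 3 endothelial (2, 1), 4 of 4 epithelial (2, 2), 4 of 4 handling and stress (4, 3), 3 of 3 mitochondrial (2, 0), 2 of 2 collagen (2, 2), 2 of 2 protease (2, 0) and 1 of 2 smooth muscle genes (1, 1). In the first 3 of these lists 1 member each was lower, and all denominators are members in the table. Counts adjusted over the list alone were the same except for smooth muscle (2). Single members of the complement, HDAC inhibitor, metallothionein and leukocyte lists were higher and positive under TMM, that of the butyrate list was higher and turned, and that of the p53 list was lower. In fits without 1 library, ACSM3 (0.38 to 0.93), HLA-DPA1 (0.87), PPARGC1A (0.72), CPT1B (0.48 to 0.59) and CLDN4 (0.92) lost their call at least once, and CIITA (−0.99), CEBPA (1.91), PHEX (0.90) and ACTG2 (0.38 to 0.51) gained one.

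Whether the effect of BA differs with cytokines was tested directly by the interaction. EGR1 (log2 −1.94 ± 0.09, SE) and FOS (−2.06 ± 0.15) had a lower BA change with cytokines than without. That of EGR1 was 2.65 without and 0.70 with cytokines, the latter turning to −0.35 under TMM inside the table, and that of FOS was 1.80 without and −0.26 with them. EGR1 was at 6735 ± 253 with both and 6719 ± 423 with BA alone (SD, n = 3), and FOS at 657.8 ± 34.5 and 736.7 ± 26.2 (SD, n = 3). TPTEP2-CSNK1E (−2.78 ± 0.58, SE) was the only other of 1839 genes called, while 194 had an unadjusted p under 0.05. Adjusted p was 1.69e-17 for EGR1, 1.2e-12 for FOS and 0.0208 for TPTEP2-CSNK1E (edgeR quasi-likelihood, BH). EGR1 and FOS were called in all 12 fits that left out 1 library. TPTEP2-CSNK1E was not called without vehicle library 1 (−2.62) or 2 (−2.80), BA library 1 (−2.36), BA with cytokine library 1 (−2.58) or 3 (−2.76), or cytokine library 3 (−2.36). The next smallest p-values in the negative direction belonged to ZBED9 (−2.75) and DUSP1 (−0.35), and in the positive direction to MYOM2 (1.56), CYCSP24 (4.19), KISS1 (1.90), SEPTIN14P2 (1.49) and C16orf71 (1.80), none of them called with all libraries. In fits without 1 library 3 genes gained a call, CYCSP24 without BA with cytokine library 2 (4.65), EGR2 without vehicle library 2 (−2.47, against −1.62 with all libraries) and TRNS1 without cytokine library 1 (1.21, against 0.62). No interferon gene was called, with a median of 0.01, nor any NF-κB gene, of which 2 passed on the negative side when adjusted over the list alone. As a set the NF-κB and TNF genes moved down in the interaction (adjusted p = 0.0164, limma's fry, BH over 12 tests), while their median was 0.00 and 9 of 19 were positive. The set was not called with scaling inside the table (adjusted p = 0.75 by TMM and 0.333 by total count, same test). Among the handling and stress genes 2 were called and 3 passed when adjusted over the list alone.

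Across the 1839 genes, the BA change with cytokines correlated with that without (Pearson 0.83, Spearman 0.72, across genes, which are not independent replicates). These 2 comparisons share no library. In both, 1090 genes were higher, where independent lists give 842.9, and 179 lower, where independent lists give 33.2. Called in opposite directions were 4. Genes entered the table by a change in comparisons that include these 2. The overlap and the correlation therefore describe the selected set and test nothing. Without the 3 libraries high in RNA45SN3 the Pearson correlation was 0.77.

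**Figure D3:**
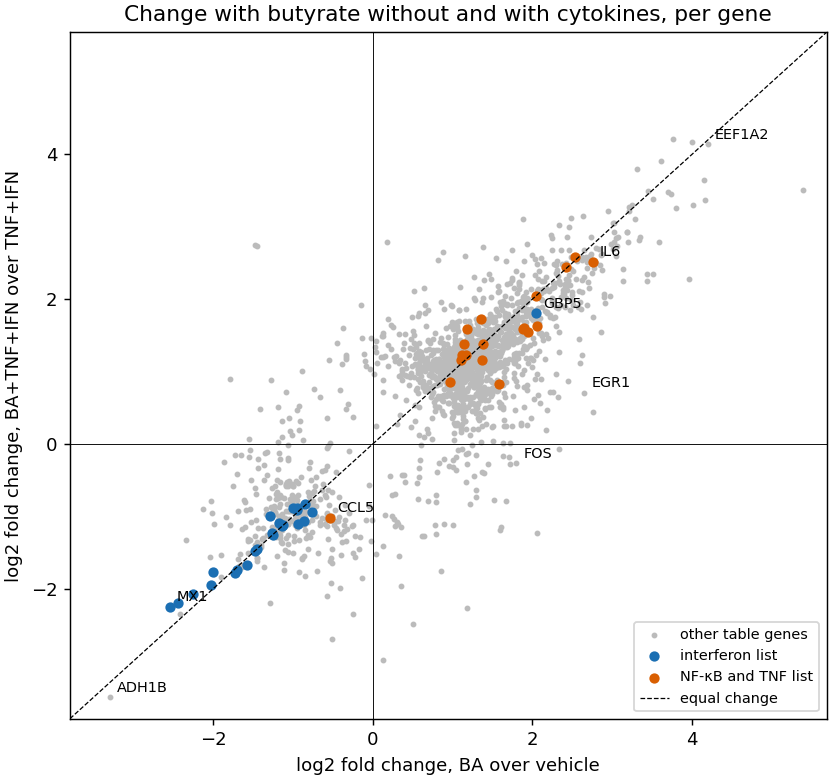
Log2 change with BA without cytokines (horizontal axis) against that with cytokines (vertical axis) for each of the 1839 table genes, with interferon list members in blue, NF-κB and TNF list members in orange and a dashed line of equal change. Most points lie along the line (Pearson 0.83), and EGR1 and FOS lie below it.

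Of the 17 genes called with cytokines against vehicle, 5 were called in the opposite direction when BA was added to cytokines (FOS, RN7SL4P, TTC3P1, TPTEP2-CSNK1E and LOC105369161) and 9 in the same direction (RCAN1, DUSP1, EGR1, F3, CXCL2, IL6, IER3, CARNS1 and NFKBIZ). EGR1 turns to the opposite direction with scaling inside the table (−0.35 by TMM, −0.25 by total count and −0.35 by DESeq2), where 6, 7 and 9 genes were called in the opposite direction. Both comparisons use the cytokine libraries, which alone pushes genes to opposite signs: 41.2% of the 17 had opposite signs, against 94.4% (82.4% to 100%) in 20 simulations without effects. The simulations held no BA effect, while all table genes had a median log2 change of 1.06 with BA in cytokine-treated cells. As 16 of the 17 genes rose with cytokines, that general rise by itself lowers the share of opposite signs. The gap therefore does not single out cytokine genes. The 5 rest on single libraries: the number was 1 without vehicle library 1 or 3 or BA with cytokine library 3, 2 without vehicle library 2 or cytokine library 3, 3 without BA with cytokine library 2 or cytokine library 2, and 11 without cytokine library 1. Between BA with cytokines and BA alone, a comparison added after the data were seen, RCAN1 was the only gene called (log2 0.32 ± 0.06, SE), a call lost without BA library 2 (0.33), BA with cytokine library 1 (0.31) or the 3 libraries high in RNA45SN3 (0.32). In the same comparison 156 genes had an unadjusted p under 0.05, and EGR1 (0.00 ± 0.07) and FOS (−0.16 ± 0.10) were not called.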

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

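The tests of 1 library, of handling and of the cytokine response for EGR1 and FOS, and the set tests (fry), were chosen after the results were seen. A BA effect that differed between cells with and without cytokines, by the interaction test, was found for EGR1 (log2 −1.94), FOS (−2.06) and TPTEP2-CSNK1E (−2.78), with adjusted p = 1.69e-17, 1.2e-12 and 0.0208 (edgeR quasi-likelihood, BH). In cells without BA all 3 genes rose with cytokines, while in cells with BA the cytokine change was 0.00 for EGR1, −0.16 for FOS and −0.86 for TPTEP2-CSNK1E, none of them called. EGR1 and FOS were called in all 12 fits without 1 library. TPTEP2-CSNK1E lost its call in 6 of them: without vehicle library 1 (−2.62) or 2 (−2.80), BA library 1 (−2.36), BA with cytokine library 1 (−2.58) or 3 (−2.76), or cytokine library 3 (−2.36). For the number of genes called, chance could not be excluded: 9 of 100 splits of the 12 libraries, the real one included, called at least 3 genes, and the highest of the others called 11.

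EGR1 and FOS are immediate-early genes, and their rise with cytokines is the first pattern weighed. The lowest change of either gene over the 6 fits without a vehicle or cytokine library was log2 1.82, which argues against 1 library as the cause. A response to the added cytokines may account for the rise. The NF-κB and TNF list moved up with cytokines both without BA (adjusted p = 1.97e-05) and with it (adjusted p = 4.44e-05, limma's fry, BH over 12 tests). With BA, however, the list's median cytokine change was only 0.07, with 14 of 19 positive and none called. EGR1 and FOS did not rise there (0.00 and −0.16), so that list result is no evidence on their rise. The interferon list left a cytokine response open (adjusted p = 0.258, same test). In the interaction the NF-κB and TNF list moved down with the authors' size factors (adjusted p = 0.0164) but was not called with TMM inside the table (adjusted p = 0.75, same test). Handling of the cultures at harvest cannot be told apart from treatment, because each group is a set of cultures of its own. The handling and stress genes had a median cytokine change of 1.22 without BA and 0.09 with BA. The BA rise of EGR1 and FOS without cytokines and their interaction use the same vehicle cultures, so the same limit holds for them.

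TPTEP2-CSNK1E is 1 of 19 read-through models in the table, a class noticed from its members, and the spread of these models between replicates is the next pattern. Their median SD of log2 scaled counts within groups was 0.71, against a median of 0.36 (0.29 to 0.44, central 95%) for 10000 random lists matched on mean level, which puts it at percentile 100. That argues against low counts alone. Reads divided differently between overlapping gene models could produce such a spread, a hypothesis tested on the data it came from, and no biological explanation was tested.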

How the results depend on the processing

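The tests chosen after the data were seen were those on log2 TPM, DESeq2 with the authors' size factors and without the 3 libraries high in RNA45SN3, and for BA with cytokines against BA, and the set tests (fry) under other scalings. Of 2677 alternative values for 146 gene results, 2502 kept direction and side of the threshold, 151 lost the call, 5 gained it and 19 turned. The 3 scalings computed inside the table moved the BA comparisons most, because they set the centre of genes selected for change near 0: in the order TMM, total count and DESeq2, the median log2 change shifted by −1.11, −0.97 and −1.10 for BA against vehicle, and by −1.05, −0.95 and −1.05 when cytokines were present. They called 695, 747 and 696 genes for BA against vehicle, 710, 752 and 695 for BA with cytokines against cytokines, and 682, 735 and 673 for BA with cytokines against vehicle. Of the genes these scalings called for BA against vehicle, 571, 642 and 574 were also called with the authors' factors, counted without regard to direction. PTX3, for example, was called lower by TMM but higher with the authors' factors. NF-κB and TNF genes called higher numbered 9, 11 and 9 for BA against vehicle, 10, 12 and 9 for BA with cytokines against cytokines, and 10, 14 and 9 for BA with cytokines against vehicle. Among those 146 gene results the ones that turned, in the same order, were PTGS2 (−0.14, −0.01 and −0.14 without and −0.19, −0.10 and −0.19 with cytokines), PTX3 without cytokines (−0.21, −0.07 and −0.20), CD74 without cytokines (−0.11 by TMM and −0.10 by DESeq2), DUSP1 without cytokines (0.00 by TMM and 0.00 by DESeq2), and with cytokines PPARG (−0.17, −0.08 and −0.17) and EGR1 (−0.35, −0.25 and −0.35). List members outside them turned as well, for example LIF, ALPL, APOE, CFI, ACSM3, HLA-DPA1 and MCAM by TMM without cytokines and MMP1, BMP6 and PHEX with them. The set tests of the NF-κB and TNF and interferon lists kept direction and side of the threshold under TMM and total count, except the interaction of the former. Log2 TPM, scaled over whole libraries, shifted the BA medians by −0.12, −0.11 and −0.10 only.

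The cytokine comparison, with 17 genes, had 10 genes with only the groups compared, 10 with limma-voom, 7 with BH over the genes the authors tested, 9 at a fold change of 2, 9 with log2 TPM, 8 without the libraries high in RNA45SN3, and 8 to 23 leaving out 1 library. Its NF-κB and TNF genes numbered 2 with only the groups compared, 2 with limma-voom, 2 with BH over the genes the authors tested, 0 at a fold change of 2, 2 without the libraries high in RNA45SN3 and 2 to 4 leaving out 1 library. Cytokine genes opposed by BA, 5 in the report, numbered 9 with DESeq2 factors of the table, 2 with only the groups compared, 2 with limma-voom, 0 with BH over the genes the authors tested, 3 at a fold change of 2, 1 with log2 TPM, 1 without the libraries high in RNA45SN3 and 1 to 11 leaving out 1 library. The interaction had 5 genes (2 positive and 3 negative) with DESeq2 under either set of factors, MYOM2 and MSANTD3-TMEFF1 in addition to the 3 reported. BA with cytokines against BA, with 1 gene, had 2 by TMM, 2 by DESeq2 factors of the table, 4 by limma-voom, 0 at a fold change of 2 and 0 to 2 leaving out 1 library; beside the counts of 0, 156 genes had an unadjusted p under 0.05 with all libraries. A larger adjustment or a minimum fold change lowers counts by construction; for the other settings the cause was not tested.

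The correlation of BA effects, 0.83, was 0.84 at a mean count of at least 10, 0.84 at a mean scaled count of at least 8, 0.85 with log2 TPM, 0.77 without the libraries high in RNA45SN3 and 0.81 to 0.82 leaving out 1 library. The label check for higher genes, 1.20, was 0.92 (TMM), 0.86 (total count), 0.91 (DESeq2), 1.26 with BH over the genes the authors tested, 1.26 at a fold change of 2, 1.12 with log2 TPM and 1.27 without the libraries high in RNA45SN3. For lower genes, −1.0, it was −1.99, −1.92, −2.0, −1.09 (BH), −1.05 (fold change of 2), −1.09 (without those libraries) and −1.05 to −1.0 leaving out 1 library. The direction held in each of these, and the cause of the smaller shifts was not tested.

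Replicate numbers did not pair the samples: over 18 pairs of libraries with the same number, correlations of deviations ran from −0.11 to 0.15, 3 were over 0.1, and 5 of 12 libraries correlated best with their own number. With the replicate number as a block the counts were 1514 for BA against vehicle, 13 for cytokines against vehicle, 1442 for BA with cytokines against cytokines, 1449 for BA with cytokines against vehicle and 3 for the interaction, and 2 cytokine genes were opposed by BA. A fit with no filter is the same as the one reported, a fit of only the groups compared is the same for the interaction, and camera was not run on a selected table. Full library depth is not known here, so genes of low count, such as GALNT17 at 2.385 with BA and cytokines, have a precision given by the replicates alone.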

Other observations

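The tests of a lost cytokine response and of the set of interferon genes (fry), the splits for BA with cytokines against BA, log2 TPM as the test of scaling, and the genes PTX3, SOD2 and TERT were chosen after the results were seen. In the authors' deposited table of pathways, 170 of 312 KEGG pathways passed a false discovery rate of 0.05 for 497 selected genes against a background of 24690, without a split by comparison or direction. Cytokine-cytokine receptor interaction (40 of 295 genes) shared the smallest FDR in the authors' deposited table, 2.93e-18, with pathways in cancer (52 of 531). By the authors' deposited fold changes 38 of the 40 were higher with BA. Of the other 4 pathways with the smallest FDR in the authors' deposited table, pathways in cancer had 50 of 52 genes higher with BA, metabolic pathways 67 of 84, rheumatoid arthritis 21 of 22 and human papillomavirus infection 31 of 36. Whether these shares differ from that of the other selected genes was not tested.

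PTX3, the gene of the secreted pattern recognition protein pentraxin 3, went from a scaled count of 72130 ± 1710 in vehicle to 135100 ± 2870 with BA (SD, n = 3), and SOD2, the mitochondrial superoxide dismutase, from 15660 ± 632 to 35160 ± 390 (SD, n = 3). Their log2 changes, 0.91 and 1.17, lie near the median of all table genes, 1.11, and under the scalings inside the table PTX3 turned negative, called lower by TMM (−0.21), while SOD2 was not called by TMM (0.06). TERT, which the line carries in its name, was at 6227 ± 66.8 in vehicle, 6235 ± 616 with cytokines, 14870 ± 2530 with BA and 15290 ± 1080 with both (SD, n = 3). Its log2 change with BA was 1.26, against 0.14 relative to the other selected genes (TMM inside the table), where it was not called. Reads of TERT are not split here by origin. Of 482 long noncoding RNAs in the table, 273 rose and 69 fell with BA, against 962 and 153 of 1232 protein-coding genes.

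The lower level of interferon genes with BA is the last pattern weighed. With log2 TPM, scaled over whole libraries, the higher of the median changes of the 24 members in both BA comparisons was log2 −1.21. That argues against the choice between log2 TPM and the authors' factors as the cause. Both were set over all genes of a library, so a change in total RNA could not be tested. The highest median in fits without 1 library was −1.09, which argues against 1 library. Scalings inside the table lower such a median by construction and test nothing here. The genes were lower without cytokines too (median −1.26), where no response to added cytokines could be lost. The median interaction of 0.01 decides nothing here. With cytokines alone the genes rose by a median of only 0.14, and none was called. Losing all of that rise would hardly move the interaction. As a set the genes moved down with BA both without and with cytokines (adjusted p = 1.97e-05 in each, limma's fry, BH over 12 tests). Only the 24 of 44 listed genes that passed the authors' selection entered this set test. Most table genes were selected for a change with BA, so the set test lends no separate support. A candidate explanation is lower basal interferon signalling in BA-treated cells, a hypothesis that these data gave and that was not tested apart from them.

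With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The table genes were also selected under the real grouping, which by itself favours calls in the real split. The real split called 1523 genes for BA against vehicle (highest other 1), 17 for cytokines against vehicle (1), 1462 for BA with cytokines against cytokines (2), 1456 for BA with cytokines against vehicle (1) and 1 for BA with cytokines against BA (1). The number of splits with as many genes, the real one included, was 1 in the first 4 and 2 in the last.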
